A study of Zea mays with 48 samples.

How the data were processed

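Polyadenylated RNA libraries from maize embryos and endosperm of the reciprocal crosses B73 by Mo17 (BM) and Mo17 by B73 (MB) were sequenced on an Illumina HiSeq. Each of the 16 groups held 3 biological replicates, per the labels, each a pool of many embryos from several ears. The genome build, the annotation release, the read counting mode and the strand setting are not given in the sources used here, so transcripts of the opposite strand cannot be told apart from those of the gene. Per the submitters' processing notes FastQC, TopHat, HTSeq and Cufflinks 2.2.1 were used, without a statement of which tool made which value. The deposited table gives raw counts per gene model in whole numbers, per the file headers, for 39656 gene models, of which 34826 had a read in some library. The same deposited table gives FPKM per gene model and library, the authors' normalised values.

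Total counts per library ran from 7130090 to 21698127, taken as the sum over all gene models. CPM is the count over that total, scaled in the usual way. Means are given with the SD over libraries. Counting intervals are 95% and, with the bounds for genes without a read (3 counts over the group), cover counting error only, since reads are not independent molecules. Gene names came from a names table of the B73 reference assembly, which matched 18775 of the gene models (47.3%) and gave 2590 an informative name; 520 gene models matched several entries. Zeins and other families of near-identical genes may share reads, so values of single members are uncertain.

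Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, estimateDisp, glmQLFit with robust settings and glmQLFTest, called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. All tests were two-sided. There were 20 comparisons, each fitted on its own libraries. Age, tissue and collection comparisons used 12 libraries with cross as an additive term, reciprocal comparisons used 3 libraries against 3, and 3 interaction terms tested whether the reciprocal difference varied with tissue, age or collection. Named genes were the 6 largest changes each way (4 for reciprocal comparisons) with adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap between conditions within either cross, a mean of at least 10 CPM and an informative name, plus the members of the fixed lists and, among genes with an informative name, the 5 called the same way in the most sample kinds (ties by the largest median change). A few of these stand in the text. Detection was counted without a test.

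Gene lists were tested for the 9 age, collection and tissue comparisons with limma 3.58.1 camera, with a preset correlation of 0.01 and with an estimated one, adjusted over lists and comparisons. Lists with fewer than 5 measured members were described without a test. There were 20 lists fixed before the data were examined. Those with members covered meristem patterning, auxin, embryo maturation regulators, embryo storage and LEA, starch, and endosperm storage regulators and zeins. They also covered basal transfer and embryo-surrounding genes, aleurone, photosynthesis, polycomb, DNA methylation, imprinted endosperm genes, ovule and seed coat, and proteases. The other 6 of the 20 relied on gene descriptions, which the names table lacks, and stayed empty. They were fatty acid and oil synthesis, replication and histones, cyclins, ribosomal proteins, heat shock and cell wall. The photosynthesis list had no tested member. For these reasons 16 lists were added from families of gene symbols after the fixed ones came out empty and before expression values were looked at; the transfer-layer set of 14 genes is the added endosperm domain list without the embryo-surrounding and ebe genes.

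The tests, thresholds, lists and naming rule were chosen before the data were examined. So were these alternatives: RLE size factors, DESeq2 1.42.0 (Wald test), no filter on low counts, at least 1 CPM in 3 libraries, the replicate number as a block, 1 fit over all 48 libraries, an absolute log2 fold change of at least 1, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, leaving out each library in turn, and for detection 0.5 CPM, 1 FPKM, 4 of 6 libraries and thinning to 7130090 counts. Chosen after seeing the data were the fit without both LCM libraries at 3 DAP that stood apart and the tests of explanations in the closing section. A fit without 2 libraries at 9 DAP was also tried and is not reported, because the libraries had been picked by their outcome. The libraries were regrouped within cross for age, tissue and collection comparisons and within sample kind for interactions, with 60 splits drawn where more than 100 exist. For reciprocal comparisons all 10 splits of the 6 libraries were used, which mix the crosses.

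The pipeline was tested on simulated counts with known changes. They were drawn from a negative binomial model with the mean shares, library totals and dispersions of the data. These draws hold no other difference between groups and no outlying libraries, so the real counts may behave less well. In the comparison of 7 and 5 DAP edgeR recovered 71.7% of genes with a true log2 change of 1 and 90% of those with 2, with 6 false calls among 22564 genes. For MB over BM at 5 DAP these shares were 63.3 and 85.9%, for the interaction with tissue 35.8 and 73.2%, for LCM at 5 against 3 DAP 3.1 and 37% and for MB over BM in LCM at 3 DAP 0 and 1.1%. The table has no counts split by parental allele, so imprinting was not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.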

Results

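Messenger RNA was sequenced from early maize kernels of a reciprocal cross between the inbred lines B73 and Mo17. BM had B73 as the seed parent and MB had Mo17 as the seed parent. Embryos were collected by laser microdissection (LCM) at 3 and 5 days after pollination (DAP) and by hand at 5, 7, 9, 11 and 13 DAP. Endosperm, the nutritive tissue next to the embryo, was collected at 5 DAP by a method that the sources used here do not give. The 8 sample kinds in 2 crosses made 16 groups of 3 biological replicates, 48 libraries in all. Total counts per library were 10436448 to 12781217 for LCM embryos at 3 DAP and 10744249 to 11654630 at 5 DAP. They were 12037753 to 15983597 for manual embryos at 5 DAP, 12098272 to 17757529 at 7 DAP, 12729767 to 18962910 at 9 DAP, 13051432 to 17583313 at 11 DAP and 12642929 to 21698127 at 13 DAP. Endosperm libraries held 7130090 to 14489244.

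Collection method, tissue and age separated the libraries in that order. The first principal component, with 53.8% of the variance over 25454 genes, parted LCM embryos from the other libraries. The second (16.8%) parted endosperm from embryo, and the third (7.7%) followed the age of the manual embryos. Replicates correlated across genes at r = 0.853 to 0.958 in the LCM groups at 3 DAP, at 0.953 or above in the LCM groups at 5 DAP and at 0.966 or above in all other groups. The 100 most abundant genes took 21.6 to 32.8% of the counts in LCM libraries, 10.2 to 14.5% in manual embryos and 17.0 to 17.9% in endosperm.

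**Figure D1:**
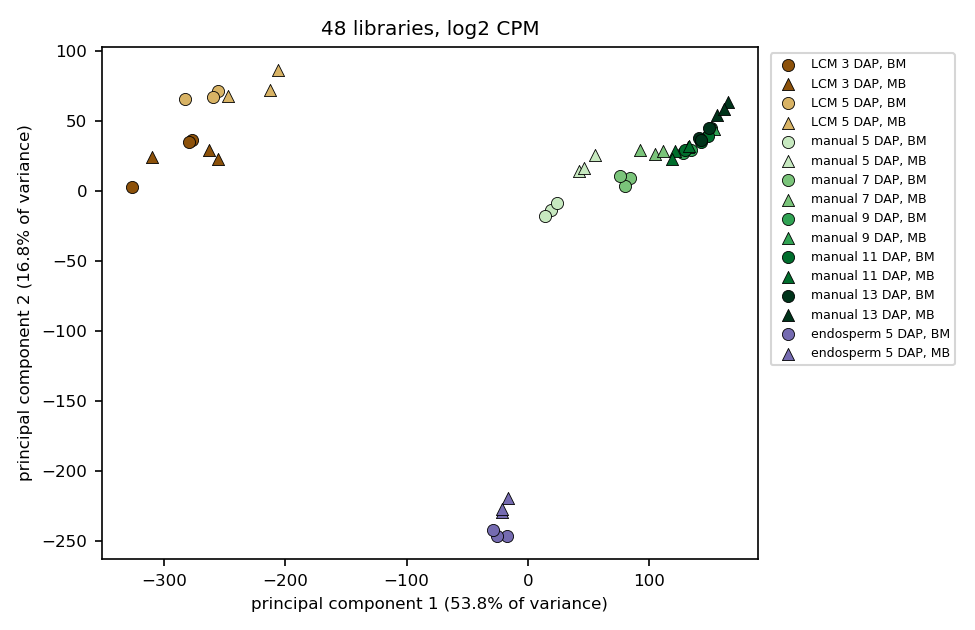
Principal components 1 and 2 of log2 CPM (counts scaled to library total) for the 48 libraries, with colour for sample kind, circles for BM and triangles for MB. LCM embryos lie at the left of component 1 (53.8% of variance) and endosperm at the bottom of component 2 (16.8%).

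The number of genes with transcripts was asked for each sample kind, because the series title names stepwise gene activation in the young embryo. A gene counted as detected where its level was at least 1 CPM in all 6 libraries of a kind. LCM embryos had 13265 such genes at 3 DAP and 15621 at 5 DAP. Manual embryos had 18685 at 5 DAP, 18573 at 7 DAP, 18107 at 9 DAP, 18640 at 11 DAP and 17982 at 13 DAP, and endosperm had 17710. Every sample kind shared 11055 genes, and 611 were detected in endosperm and in no embryo kind. Relative to all younger ages of the same collection, 2947 genes were newly detected in LCM embryos at 5 DAP, 854 in manual embryos at 7 DAP, 396 at 9 DAP, 396 at 11 DAP and 85 at 13 DAP. Those of LCM embryos at 5 DAP included the auxin response repressor IAA12 (GRMZM2G128421, 36.5 CPM) and the auxin efflux carrier PIN1d (GRMZM2G171702, 31 CPM). At 7 DAP they included the YABBY transcription factor yab14 (GRMZM2G005353, 104 CPM), the shoot meristem homeobox gene kn1 (GRMZM2G017087, 73.5 CPM), the globulin GRMZM2G067919 (48.8 CPM), the gamma zein gz27 (GRMZM2G138727, 28.8 CPM) and the sucrose transporter sut1 (GRMZM2G034302, 25 CPM). Other storage genes met the rule later. The globulin glb2 (GRMZM2G026703, 102 CPM) and the oleosin ole17 (GRMZM2G480954, 18.8 CPM) met it at 9 DAP. The alpha zein fl2 (GRMZM2G397687, 156 CPM) and the transcription factor o2 (GRMZM2G015534, 15.3 CPM) met it at 11 DAP. First detection depends on the cross for some of these: kn1 was at 77.5 ± 6.93 CPM (SD, n = 3) in MB embryos by 5 DAP and at 0.756 ± 0.116 CPM in BM embryos. It also depends on the rule that all 6 libraries pass. In manual embryos at 5 DAP gz27 was at 0.415 CPM in BM replicate 2 and at 1.2 to 2.99 CPM in the other libraries. At 7 DAP glb2 was at 1.52 to 4.97 CPM in MB and at 1.23 CPM in BM replicate 3. The 5 DAP LCM count of 2947 fell to 1853 without replicate 3 of the 4 LCM groups and to 1222 when 4 of 6 libraries sufficed.

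Changes from here on are log2 fold changes ± SE with edgeR adjusted p, from 6 libraries per condition for age, tissue and collection and from 3 per cross for MB over BM. Gene lists given without a p had fewer than 5 members or an adjusted p of at least 0.05 with a preset correlation.

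In embryos isolated by laser, heat shock genes and some genes abundant in endosperm were among those that fell between 3 and 5 DAP. The auxin synthesis genes Yucca6 (GRMZM2G019515, -6.29 ± 0.7, adjusted p = 0.00025) and Yucca3 (GRMZM2G107761, -4.87 ± 0.83, adjusted p = 0.0032) fell, Yucca6 from 172 ± 153 to 2.43 ± 2.2 CPM. The polycomb gene fie1 (GRMZM2G118205) also fell (-4.42 ± 0.46, adjusted p = 0.00016). Both Yucca6 (156 ± 14.1 CPM) and fie1 (357 ± 62.1 CPM) were abundant in endosperm at 5 DAP (SD, n = 6). Other endosperm transcripts went the same way: gz27 went from 5.39 to 0.759 CPM. The sum of 14 genes of the transfer layer, an endosperm cell type, went from 64.5 to 13.6 CPM, although in BM it was under 3 CPM in every LCM library. The small heat shock gene hsp18c (GRMZM2G034157, -5.11 ± 0.7, adjusted p = 8e-04) fell as well. The inositol phosphate kinase gene ipk1A (GRMZM2G067299, 2.15 ± 0.31, adjusted p = 0.0011) and the embryo-surrounding region gene esr1 (GRMZM2G046086, 2.06 ± 0.39, adjusted p = 0.0053) rose. Of 22 heat shock genes 9 fell and 1 rose, of 28 ribosomal protein genes 7 fell, and of 19 cell wall genes 5 fell and 1 rose. The set tests of these 3 lists gave adjusted p = 0.0047, 0.0022 and 0.013 with a preset correlation, but adjusted p = 0.483, 0.483 and 0.469 with an estimated correlation. Among 36 auxin genes 7 rose, such as ARF2 (GRMZM2G153233) at 1.51 ± 0.23, and 7 fell (median 0.42, adjusted p = 0.227). In the basal transfer and embryo-surrounding list 1 member rose and 1 fell of 10, or 5 adjusted over the list alone. One starch gene fell of 4 (2 adjusted over the list alone), 1 aleurone gene rose of 4 (1 adjusted over the list alone; not without MB LCM 5 DAP replicate 2) and fie1 was the polycomb member that fell of 5 (1 adjusted over the list alone). In all, 1993 of 20168 genes changed (574 higher, 1419 lower at 5 DAP). The split was 5021 higher and 5093 lower in 1 fit over all libraries and 1636 and 1043 on FPKM. The count was 1112 or 1131 without BM LCM 5 DAP replicate 1 or 3, 1109 or 1220 without MB LCM 5 DAP replicate 2 or 3, 3613 by DESeq2 and 3024 without both 3 DAP libraries that stood apart (BM replicate 3, MB replicate 1).

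Between 5 and 7 DAP zein and oil gene transcripts rose and transcripts of endosperm domains fell in the libraries of manual embryos. The zein gz27 (3.85 ± 0.48, adjusted p = 0.00012), sut1 (3.14 ± 0.46, adjusted p = 0.00036) and the pyruvate orthophosphate dikinase gene C4ppdkZm1 (GRMZM2G306345, 3.08 ± 0.35, adjusted p = 7.4e-05) rose. The phosphate transporter pht7 (GRMZM2G112377, -3.4 ± 0.25, adjusted p = 1.5e-06), the response regulator RR3 (GRMZM2G035688, -2.49 ± 0.21, adjusted p = 1.9e-06) and ebe2 (GRMZM2G167733), a gene of the embryo sac and basal endosperm (-2.62 ± 0.5, adjusted p = 0.0023), fell. All 12 zein genes tested rose (median 3.45, adjusted p = 0.0022, but adjusted p = 0.656 with an estimated correlation), although related zeins may share reads. Of 11 oil genes 7 rose (median 0.75, adjusted p = 0.0022, but adjusted p = 0.483 with an estimated correlation), among them the acetyl-CoA carboxylase gene Acc-1 (GRMZM5G858094) at 1.16 ± 0.12. Of the endosperm domain genes 8 of 20 fell (adjusted p = 0.0001, but adjusted p = 0.684 with an estimated correlation), and so did 5 of the 11 in the basal transfer and embryo-surrounding list (5 adjusted over the list alone), betl3 (GRMZM2G175976) by -1.99 ± 0.45. Of these calls esr2 (GRMZM2G315601) and esr3 (GRMZM2G140302) were lost without any 1 of the BM 7 DAP replicates and without MB 7 DAP replicate 1 or 2, and esr2 also without any 1 of the 5 DAP libraries. That list had adjusted p = 0.0023, but adjusted p = 0.789 with an estimated correlation. Starch genes rose in 4 of 7 cases (5 adjusted over the list alone), led by the ADP-glucose transporter bt1 (GRMZM2G144081) at 2.89 ± 0.43 (list adjusted p = 0.463). The rise of bt2 (GRMZM2G068506) was lost in 1 fit over all libraries, on FPKM and on leaving out 1 library in 9 of 12 cases. Sugar cleavage and transport genes went both ways, with 4 of 10 higher and 2 lower (median -0.13, adjusted p = 0.885). All 3 measured endosperm storage regulators and zeins rose (3 adjusted over the list alone), and in the meristem list 2 rose and 3 fell of 10 (5 adjusted over the list alone), the stem cell gene wus1 (GRMZM2G047448) by -2.98 ± 0.61. Among these, the falls of wox2a (GRMZM2G108933) and fea2 (GRMZM2G104925) were both lost without MB 5 DAP replicate 1 or BM 7 DAP replicate 1, and the rise of lg3 (GRMZM2G087741) without BM 5 DAP replicate 1. The fall of wox2a was lost in 13 settings, among them RLE size factors, no filter, FPKM and leaving out any 1 MB library. That of fea2 was also lost in 1 fit over all libraries. Summed over the 14 transfer-layer genes, levels went from 3096 CPM at 5 DAP to 1179 CPM at 7 DAP, means over crosses that differed. In all, 9333 of 22972 genes changed (4504 higher, 4829 lower), 2833 of them by a log2 fold change of at least 1, and 5240 changed in 1 fit over all libraries.

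Between 7 and 9 DAP endosperm storage regulators rose while homeobox and ribosomal protein genes fell. The globulin glb2 rose most among the named genes (5.8 ± 0.45, adjusted p = 7.9e-06), followed by the oleosin ole1 (GRMZM2G337229, 3.12 ± 0.54, adjusted p = 0.0014), C4ppdkZm1 (2.77 ± 0.27, adjusted p = 2e-05) and the phosphoenolpyruvate carboxylase kinase PPCK1 (GRMZM2G178074, 2.29 ± 0.31, adjusted p = 0.00014). The transcription factors bHLH116 (GRMZM2G042895, -7.93 ± 0.64, adjusted p = 8e-06) and bHLH76 (GRMZM2G112629, -3.91 ± 0.2, adjusted p = 1.5e-08) and the glutathione S-transferase gst23 (GRMZM2G416632, -3.44 ± 0.28, adjusted p = 5.1e-06) fell. In the meristem list 6 fell and 1 rose of 9 (7 adjusted over the list alone), wox2a by -1.85 ± 0.18 and kn1 by -1.06 ± 0.14, a call that like those of lg4 (GRMZM2G094241) and td1 (GRMZM2G300133) was lost in 1 fit over all libraries (list adjusted p = 0.087). The 1 rise, of fea3 (GRMZM2G166524), was lost in that fit and without BM 7 DAP replicate 1 or 2 or BM 9 DAP replicate 2. Homeobox and YABBY genes fell in 16 of 32 cases and rose in 3 (adjusted p = 0.0085, but adjusted p = 0.606 with an estimated correlation). Of 18 cytokinin genes 9 fell and 2 rose, RR3 by -4.26 ± 0.3 (list adjusted p = 0.0515). Ribosomal protein genes fell in 23 of 28 cases by a small amount (median -0.42, adjusted p = 1.8e-06, but adjusted p = 0.569 with an estimated correlation). The embryo regulator lec1 (GRMZM2G011789) fell (-1.01 ± 0.23, adjusted p = 0.0053), the 1 called member of 2 maturation regulators (1 adjusted over the list alone). The endosperm storage regulators rose in 4 of 5 cases (4 adjusted over the list alone), with o2 at 2.36 ± 0.38 and pbf1 (GRMZM2G146283) at 1.89 ± 0.47. That list had adjusted p = 0.01, but adjusted p = 0.346 with an estimated correlation. Of 13 zein genes 3 rose (adjusted p = 0.006, but adjusted p = 0.684 with an estimated correlation). Embryo storage and LEA genes rose in 2 of 4 cases and fell in 1 (3 adjusted over the list alone), and this fall, of rab17 (GRMZM2G079440), was lost without a filter, in 1 fit over all libraries and on leaving out 1 library in 7 of 12 cases. In the wider storage list 4 of 8 rose and 2 fell (adjusted p = 0.161). Starch genes rose in 5 of 7 cases and 1 fell (6 adjusted over the list alone), and wx1 (GRMZM2G024993), a starch synthase, stood at 2.98 ± 0.72 (list adjusted p = 0.149). In all, 8722 of 22316 genes changed (4259 higher, 4463 lower), 2522 of them by at least 1, and 4731 changed in 1 fit over all libraries. That fit gave 1713 higher and 3018 lower, and FPKM gave 2697 and 4374.

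Between 9 and 11 DAP zein, starch and embryo storage genes rose. All 14 zein genes tested rose (median 3.73, adjusted p = 8.4e-10, but adjusted p = 0.483 with an estimated correlation), among them azs22-5 (GRMZM2G045387, 3.73 ± 0.73, adjusted p = 0.0063) and fl2 (4.03 ± 0.87, adjusted p = 0.0098), whose relatives may share reads. Starch genes rose in 6 of 7 cases (6 adjusted over the list alone), wx1 by 3.02 ± 0.44, adjusted p = 0.0019 and bt1 by 2.59 ± 0.57 (list median 1.63, adjusted p = 0.00072, but adjusted p = 0.417 with an estimated correlation). The endosperm storage regulators rose in 4 of 5 cases (4 adjusted over the list alone), with o2 at 2.51 ± 0.51 (list adjusted p = 0.0062, but adjusted p = 0.346 with an estimated correlation). The zein gz27 is abundant in endosperm too: it stood at 633 ± 230 CPM in embryos at 11 DAP and at 937 ± 440 CPM in endosperm at 5 DAP (SD, n = 6). Embryo storage and LEA genes rose in 3 of 4 cases (4 adjusted over the list alone), and in the wider storage list 6 of 9 rose (adjusted p = 6e-06, but adjusted p = 0.469 with an estimated correlation). Of these the globulins glb2 (1.77 ± 0.13) and glb3 (GRMZM2G410134, 3.7 ± 0.34) rose, as did ole17 (2.57 ± 0.36). Oil genes rose in 6 of 11 cases and aquaporins in 3 of 11 (adjusted p = 0.047 and 0.021, but adjusted p = 0.506 and 0.569 with an estimated correlation). Chromatin genes fell in 19 of 50 cases and rose in 2, by small amounts (median -0.25, adjusted p = 1.3e-05, but adjusted p = 0.483 with an estimated correlation), and in the DNA methylation list 3 of 4 fell (4 adjusted over the list alone). The telomerase gene TERT (GRMZM2G167338) fell (-1.32 ± 0.15, adjusted p = 0.00012). In all, 5722 of 21990 genes changed (2845 higher, 2877 lower). Of the 965 that changed by at least 1, 835 rose and 130 fell, and 2359 changed in 1 fit over all libraries.

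Between 11 and 13 DAP fewer genes changed than over any earlier manual interval. The ferritin gene fer1 (GRMZM2G325575) rose (1.03 ± 0.15, adjusted p = 0.015). The globulin glb2 was at 351 ± 53.8 CPM at 11 DAP and 801 ± 356 CPM at 13 DAP (SD, n = 6; 1.15 ± 0.23, adjusted p = 0.025). The result for glb2, embryo 13 vs 11 DAP, had adjusted p = 0.072, 0.06 or 0.076 without MB 11 DAP replicate 1, 2 or 3 and 0.052, 0.051 or 0.063 without MB 13 DAP replicate 1, 2 or 3. Of 10 cyclin genes, cyclin8 (GRMZM2G138886) fell (-0.69 ± 0.1, adjusted p = 0.015), and the list had adjusted p = 0.022, but adjusted p = 0.469 with an estimated correlation. The lists of basal transfer genes (median -2.22 over 10), endosperm domains (median -2.14 over 19) and meristem genes (median -0.35 over 9) had adjusted p = 0.00038, 5.4e-07 and 0.019. With an estimated correlation they had adjusted p = 0.789, 0.569 and 0.789. No member of these 3 lists was called by edgeR over all genes, although 6346 genes had an unadjusted p under 0.05 and DESeq2 called 3422 genes. Adjusted over the list alone 3 meristem genes passed. The lists of zeins (median -0.74; 2 of 15 fell), ribosomal proteins (median -0.17; 1 of 28 fell) and homeobox and YABBY genes (median -0.2; 1 of 29 rose and 1 fell) had adjusted p = 0.021, 0.014 and 0.022. With an estimated correlation they had adjusted p = 0.777, 0.779 and 0.688. In the ovule and seed coat list 2 of 4 fell (3 adjusted over the list alone), the MADS-box genes zag2 (GRMZM2G160687) and GRMZM2G359952, and both calls were lost without any 1 of the 6 MB libraries, zag2 also without BM 11 DAP replicate 2 and GRMZM2G359952 also without replicate 2 or 3 of BM at either age. In all, 1394 of 21774 genes changed (782 higher, 612 lower), 199 of them by at least 1 (34 higher, 165 lower), and 1 fit over all libraries gave 247 higher and 1095 lower. The count rested on single libraries: it was 3066 without BM 11 DAP replicate 1, 180, 185 or 203 without MB 11 DAP replicate 1, 2 or 3, 2171 or 874 without BM 13 DAP replicate 1 or 3, and 257, 170 or 106 without MB 13 DAP replicate 1, 2 or 3.

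Across the whole manual series, from 5 to 13 DAP, transfer-layer transcripts fell and storage transcripts rose in the libraries of manual embryos. Endosperm was sampled at 5 DAP only, so endosperm carried over could not be assessed for the later zein, starch and o2 rises. The globulin glb2 went from 0.695 to 801 ± 356 CPM (SD, n = 6; 10.18 ± 0.62, adjusted p = 2.1e-07) and ole17 rose by 9.97 ± 0.56, adjusted p = 7.7e-08. At 13 DAP o2 was 499 times its 5 DAP level (95% counting interval 89.6 to 19700) and ZCN9 (GRMZM2G021614), of the flowering-time PEBP family, was 736 times its 5 DAP level (252 to 3570). All 15 zein genes rose (median 8.73, adjusted p = 5e-09, but adjusted p = 0.469 with an estimated correlation), and so did all 5 endosperm storage regulators (5 adjusted over the list alone; median 4.96, adjusted p = 0.0031, but adjusted p = 0.346 with an estimated correlation). Of 11 oil genes 8 rose and 3 fell (adjusted p = 0.008, but adjusted p = 0.483 with an estimated correlation), with the transcription factor EREB85 (GRMZM2G124524) at 4.55 ± 0.25 and the desaturase fad7 (GRMZM2G128971) at -2.38 ± 0.06. Of 10 aquaporins 7 rose and 1 fell (adjusted p = 0.024, but adjusted p = 0.569 with an estimated correlation), TIP3-2 (GRMZM2G103983) by 9.25 ± 0.39. Phosphate transporter pht7 (-10.63 ± 0.36, adjusted p = 3.5e-11) and ebe2 (-7.96 ± 0.19, adjusted p = 9.7e-14) fell, as did 10 of 11 basal transfer and embryo-surrounding genes (10 adjusted over the list alone; median -4.52, adjusted p = 0.00028, but adjusted p = 0.725 with an estimated correlation). The wider endosperm domain list fell in 19 of 20 cases (adjusted p = 3.6e-08, but adjusted p = 0.483 with an estimated correlation). Of the ovule and seed coat genes 5 fell and 1 rose of 6 (6 adjusted over the list alone), zag2 by -4.21 ± 0.33. The maturation regulator lec1 fell (-2.43 ± 0.48, adjusted p = 0.0012), while vp1 (GRMZM2G133398) was at 186 ± 48.2 CPM at 5 DAP and 139 ± 31.6 CPM at 13 DAP. In all, 14658 of 23141 genes changed (7017 higher, 7641 lower), 6654 of them by at least 1.

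**Figure D2:**
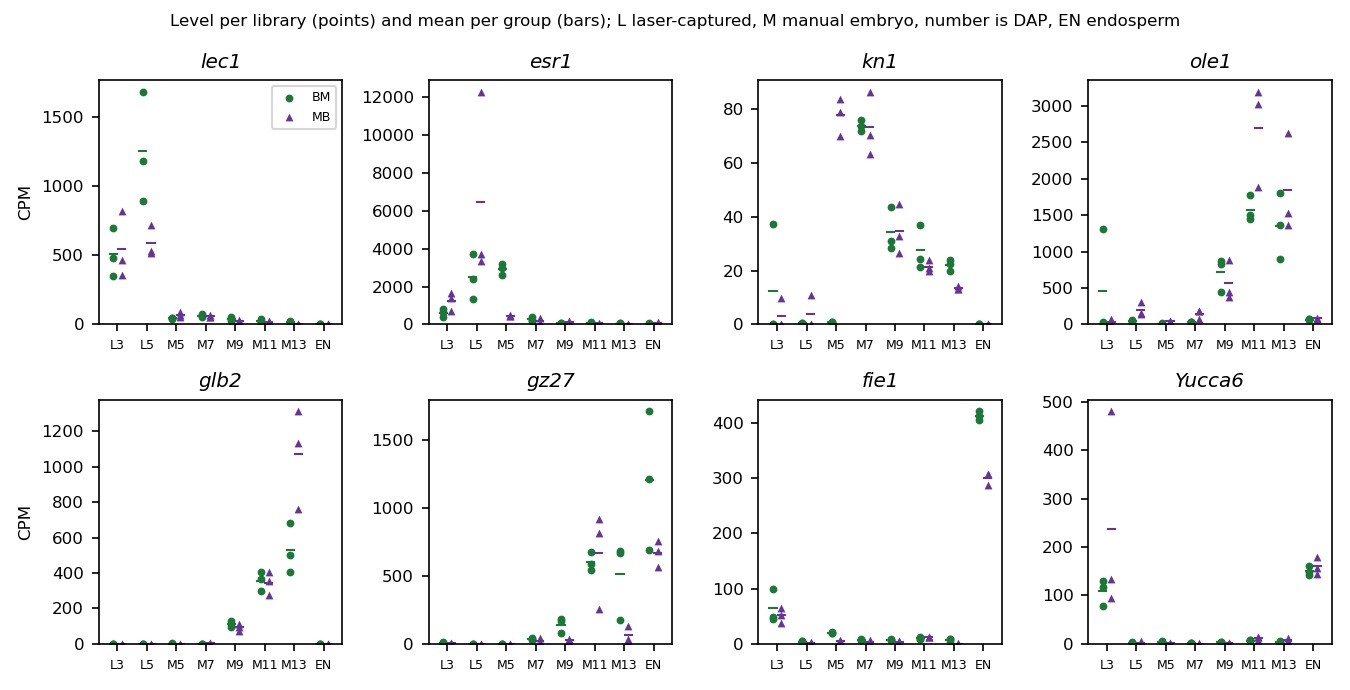
Level in CPM of 8 named genes in each library (circles BM, triangles MB) with a bar for each group mean, by sample kind on the horizontal axis. The globulin glb2 stood at 801 CPM at 13 DAP, and kn1 at 5 DAP stood at 77.5 CPM in MB and 0.756 CPM in BM.

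**Figure D3:**
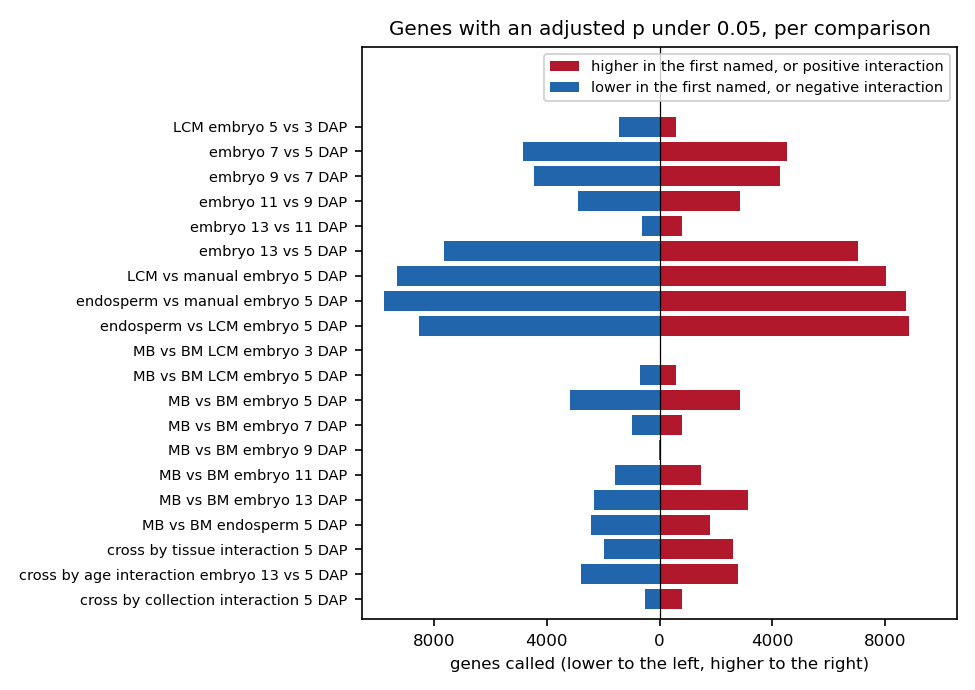
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with bars to the right for higher in the first-named condition and to the left for lower. Counts run from 3 for MB over BM in LCM embryos at 3 DAP to 18499 for endosperm over manual embryo.

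Embryos of the same age, 5 DAP, collected by laser and by hand differed in embryo regulators, replication genes and transfer-layer genes. The embryo regulator lec1 stood at 922 ± 449 CPM in LCM and 57.7 ± 17.6 CPM in manual embryos (SD, n = 6; 4.71 ± 0.38, adjusted p = 1.3e-07). Higher in LCM were also Ea1 (GRMZM2G456746), a pollen tube attractant gene of the egg apparatus (5.83 ± 0.46, adjusted p = 6.7e-08), and the storage gene ole1 (2.98 ± 0.3). Histone and replication genes were higher in 15 of 21 cases and lower in 3 (median 1.48, adjusted p = 0.014, but adjusted p = 0.517 with an estimated correlation), pcna2 (GRMZM2G108712) by 2.61 ± 0.14. Lower in LCM were transfer-layer genes. At least 4520-fold lower was bap-3b (GRMZM2G133370) and at least 639-fold lower was the transfer-cell response regulator tcrr-1 (GRMZM2G016145). Both had no read in LCM libraries at 5 DAP, and the cell wall invertase mn1 (GRMZM2G119689) was 5420 times lower (972 to 214000). Such losses were not limited to this layer. The heat shock list gene GRMZM2G458208 had 2 reads in LCM and 15186 in manual embryos, and the chromatin list gene GRMZM2G024466 had 0 and 1365. Whether the collection method causes such losses was not tested. In the basal transfer and embryo-surrounding list 6 were lower and 1 (esr1) higher of 11 (7 adjusted over the list alone; esr1 was lost on FPKM and without any 1 MB manual replicate), and in the wider domain list 14 were lower and 2 higher of 20 (adjusted p = 0.017, but adjusted p = 0.779 with an estimated correlation). The summed level of 14 transfer-layer genes at 5 DAP was 13.6 CPM in LCM embryos, a mean carried by MB replicate 3 (77 CPM, against 1.68 CPM or less in the others). It was 5376 ± 363 CPM in BM and 816 ± 25.4 CPM in MB manual embryos, and 3136 ± 525 CPM in BM and 408 ± 299 CPM in MB endosperm (SD, n = 3). The 4 imprinted endosperm genes were all lower in LCM (4 adjusted over the list alone; median -4.44, or -3.5 with members without reads at their bound), as were 4 of 5 polycomb genes (5 adjusted over the list alone). mez1 (GRMZM2G157820), in both lists, was not called on FPKM. Both auxin genes and both maturation regulators listed by symbol were higher (2 adjusted over the list alone in each case; the auxin gene bif2 (GRMZM2G171822) not on FPKM). In the meristem list 6 were lower and 1 higher of 10 (7 adjusted over the list alone), of which kn1 and ns1 (GRMZM2G069028) were lost with DESeq2. Ribosomal protein genes were higher in 18 of 28 cases on counts (median 0.66, adjusted p = 0.0072, but adjusted p = 0.683 with an estimated correlation), a direction that turned to -0.12 on FPKM. In all, 17321 of 22660 genes differed (8028 higher, 9293 lower in LCM), against 4887 and 11314 on FPKM. The median of all genes was -0.15 in the main fit, -0.63 on FPKM, -0.39 without a filter and -0.19 with RLE size factors, so smaller changes have no firm sign.

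Endosperm and manual embryo at 5 DAP differed in reserve, cell identity and chromatin genes. Higher in endosperm were gz27 (9.22 ± 0.4, adjusted p = 1.9e-09), the aquaporin PIP2-4 (GRMZM2G154628, 8.13 ± 0.2, adjusted p = 2.2e-13), bt1 (7.57 ± 0.43, adjusted p = 1.1e-08), the legumin leg1 (GRMZM2G174883, 6.55 ± 0.21) and fie1 (5.43 ± 0.28, adjusted p = 5.2e-09), which stood at 357 ± 62.1 CPM against 12.8 ± 8.19 CPM. Lower in endosperm were the asparagine synthetase gene asn2 (GRMZM2G093175, -11.72 ± 0.79, adjusted p = 1.1e-07), lec1 (-6.94 ± 0.26, adjusted p = 7.2e-12) and kn1 (-8.1 ± 0.54). The changes of asn2 and kn1 are averages over crosses that differed in manual embryos. For kn1, BM embryos stood at 0.621 to 0.831 CPM and BM endosperm at 0 to 0.175 CPM, against 70.1 to 83.8 CPM in MB embryos. The homeobox gene wox9A (GRMZM2G133972) was at least 311-fold lower, the YABBY gene yabby15 (GRMZM2G529859) 2190 times lower (95% counting interval 394 to 86700) and RR3 887 times lower (303 to 4300). Homeobox and YABBY genes were lower in 24 of 31 cases and higher in 7 (median -5.1, or -4.89 at the bound; adjusted p = 0.0091, but adjusted p = 0.483 with an estimated correlation). In the meristem list 7 were lower and 3 higher of 10 (10 adjusted over the list alone). Of these lg4 was lost with RLE size factors, DESeq2, no filter, 1 fit over all libraries and on leaving out 1 library in 8 of 12 cases, ns1 with DESeq2 and in that fit, and fea3 on FPKM. In the same comparison both maturation regulators were lower (2 adjusted over the list alone). Chromatin genes were lower in 39 of 50 cases and higher in 4 (adjusted p = 0.0015, but adjusted p = 0.469 with an estimated correlation), and all 4 DNA methylation genes were lower (4 adjusted over the list alone). Ribosomal protein genes were higher in 27 of 28 cases (median 0.95, adjusted p = 1.1e-07, but adjusted p = 0.483 with an estimated correlation) and heat shock genes in 18 of 24 (adjusted p = 0.048, but adjusted p = 0.469 with an estimated correlation). In the basal transfer and embryo-surrounding list 6 of 11 were lower in endosperm (5 adjusted over the list alone), esr1 by -4.51 ± 0.97, adjusted p = 0.0015. Of these calls meg1 (GRMZM2G354335) and betl2 (GRMZM2G152655) were both lost without a filter, in 1 fit over all libraries and without endosperm replicate 1 of BM or MB, and meg1 also on FPKM, without any 1 manual embryo library and without BM endosperm replicate 3. All 5 ovule and seed coat genes were lower in endosperm (5 adjusted over the list alone), and the protease gene see1 (GRMZM2G038636) was higher (1 adjusted over the list alone). In all, 18499 of 23153 genes differed (8739 higher, 9760 lower), 11222 of them by at least 1. The median of all genes was -0.08 in the main fit, -0.26 on FPKM, -0.25 without a filter, -0.19 in 1 fit over all libraries and -0.12 with DESeq2.

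Against LCM embryos, many transfer-layer genes, zeins and imprinted genes were higher in endosperm, and auxin and homeobox genes were lower. How endosperm was collected is not given, so tissue and collection may differ together here and cannot be told apart. The heat shock list gene GRMZM2G458208, with 2 reads in LCM embryos and 15186 in manual embryos, had 18459 in endosperm. Higher in endosperm were mn1, 10400 times the LCM level (1870 to 412000), bap-3b, at least 1730-fold, bt1, at least 1410-fold, tcrr-1, at least 502-fold, and fie1 (6.46 ± 0.38, adjusted p = 1.9e-09). In the basal list 6 were higher and 3 lower of 11 (9 adjusted over the list alone), with meg1 at 8.21 ± 0.95 and esr1 at -7.16 ± 0.84, and in the wider domain list 14 were higher and 4 lower of 20 (adjusted p = 0.63 and 0.0964 for these lists). All 4 imprinted endosperm genes were higher (4 adjusted over the list alone; median 7.33), although mez1 turned to -0.58 on FPKM, all 4 zeins tested were higher (median 9.54, or 8.58 at the bound) and starch genes were higher in 6 of 7 cases and lower in 1, which was lost on FPKM (7 adjusted over the list alone; adjusted p = 0.234). Sugar cleavage and transport genes were higher in 8 of 10 cases (adjusted p = 0.127), with sut1 at 4.87 ± 0.35. Lower in endosperm were lec1 (-11.66 ± 0.47, adjusted p = 3.7e-11), OFP24 (GRMZM2G100133, -12.11 ± 0.49, adjusted p = 4e-11), Ea1, at least 861-fold, and wox9A, at least 496-fold. Auxin genes were lower in 23 of 39 cases and higher in 9 (adjusted p = 0.044, but adjusted p = 0.469 with an estimated correlation), with IAA12 784 times lower (268 to 3800) and Yucca6 at 5.63 ± 0.46. Homeobox and YABBY genes were lower in 14 of 22 cases and higher in 3 (adjusted p = 0.047, but adjusted p = 0.483 with an estimated correlation). In all, 17356 of 21862 genes differed (8830 higher, 8526 lower), against 9914 and 5988 on FPKM. The median of all genes was 0.05 in the main fit, 0.42 on FPKM and 0.1 with RLE size factors.

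The reciprocal comparison, MB over BM at each sample kind, addresses parent-of-origin effects, although total counts cannot tell the parental alleles apart and the seed parent and cytoplasm differ together with the cross. Endosperm holds more genome copies from the seed parent than from the pollen parent. The dose of each line's genome there differs between the crosses as well, so a difference in endosperm need not be a parent-of-origin effect. In LCM embryos at 3 DAP 3 genes were called, all higher in MB and named here after their values were seen: GRMZM2G472096 (6.15 ± 0.59, adjusted p = 0.03; 169 against 2.28 CPM), GRMZM2G027472 (24.9 against 0 CPM, adjusted p = 0.041) and GRMZM2G121137 (107 against 0.111 CPM, adjusted p = 0.041). edgeR called 0 genes without BM replicate 1, 2 or 3 and 1 without MB replicate 1. At unadjusted p under 0.05 there were 1502 of 18597 genes, DESeq2 called 292 and limma on FPKM 23. On simulated data edgeR recovered 1.1% of genes with a true log2 change of 2 in this comparison.

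In LCM embryos at 5 DAP the auxin response repressor IAA12 was among the genes with the largest difference. It stood at 70.8 ± 20.9 CPM in MB and 2.14 ± 0.683 CPM in BM (SD, n = 3; 4.8 ± 0.3, adjusted p = 5.7e-05), and EREB36 (GRMZM2G069082), of the ethylene-responsive element binding family, was higher (2.58 ± 0.42, adjusted p = 0.01), as was yabby15, at least 222-fold. The potassium transporter HAK1 (GRMZM2G093826, -2.24 ± 0.23, adjusted p = 0.0016) and the chaperone gene Hsp70 (GRMZM2G310431, -2.15 ± 0.33, adjusted p = 0.0079) were lower. In all, 1289 of 18511 genes differed (582 higher, 707 lower in MB), against 876 and 421 on FPKM, 2250 by DESeq2 and 3630 in 1 fit over all libraries. The count was 401, 507 or 547 without BM replicate 1, 2 or 3 and 239 or 388 without MB replicate 2 or 3.

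In manual embryos at 5 DAP asn2, kn1 and yab14 were among the genes higher in MB, and transfer-layer genes were lower. In MB asn2 stood at 1730 ± 19.1 CPM and in BM at 4.17 ± 0.711 CPM (SD, n = 3; 8.61 ± 0.09, adjusted p = 9.6e-15). Higher in MB were also kn1 (6.58 ± 0.16, adjusted p = 1.3e-11) and yab14 (5.64 ± 0.18, adjusted p = 8e-11). The homeobox gene ns1, at least 49-fold, was higher as well. Lower in MB were tcrr-1 (-4.44 ± 0.16, adjusted p = 2.6e-10), betl3 (-3.49 ± 0.1, adjusted p = 2.8e-11) and mn1 (-3.29 ± 0.09, adjusted p = 2.7e-11). The 14 transfer-layer genes summed to 816 ± 25.4 CPM in MB and 5376 ± 363 CPM in BM. In all, 6005 of 22060 genes differed (2839 higher, 3166 lower), 1955 of them by at least 1, against 3754 and 1787 on FPKM and 1546 genes in 1 fit over all libraries.

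At 7 DAP the difference between crosses was smaller. Higher in MB was sfp1 (GRMZM2G159632, 2.93 ± 0.21, adjusted p = 0.0019), and the superoxide dismutase gene Sod4A (GRMZM2G058522) was lower (-1.56 ± 0.1, adjusted p = 4.9e-05), at 100 ± 14.5 against 284 ± 14.7 CPM (SD, n = 3). The level of asn2 was 755 ± 605 CPM in MB and 3.71 ± 0.451 CPM in BM (7.61 ± 0.88, adjusted p = 0.019). The result for asn2, MB vs BM embryo 7 DAP, had adjusted p = 0.094, 0.098 or 0.081 without BM replicate 1, 2 or 3 and 0.054 without MB replicate 2. Transfer-layer genes summed to 575 ± 541 CPM in MB, where replicate 3 stood at 1187 CPM and the others at 376 and 163 CPM, and to 1783 ± 373 CPM in BM. In all, 1794 of 21560 genes differed (804 higher, 990 lower), 475 of them by at least 1, against 594 and 476 on FPKM and 241 genes in 1 fit over all libraries. Without BM replicate 1, 2 or 3 the count was 608, 419 or 1058, and without MB replicate 1, 2 or 3 it was 920, 778 or 3492.

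At 9 DAP edgeR called 6 genes, 3 each way, all at adjusted p = 0.039 and named after their values were seen. mips2 (GRMZM2G004528), a myo-inositol phosphate synthase gene, was higher in MB (0.67 ± 0.08; 1880 against 1200 CPM), as were gigz1b (GRMZM5G844173, 0.95 ± 0.11) and GRMZM2G107499 (1.47 ± 0.16). Lower were hag (GRMZM2G304548, -1.68 ± 0.18), GRMZM2G159171 (-0.97 ± 0.11) and GRMZM5G871471 (-4.66 ± 0.54). Another split of these 6 libraries, BM replicate 1 with MB replicates 1 and 2 against the rest, gave 1766 genes. At unadjusted p under 0.05 there were 1633 of 20712 genes, DESeq2 called 127, limma on FPKM 1 and edgeR without a filter 50. edgeR called 0 genes without BM replicate 2 or 3, 1 or 2 without MB replicate 1 or 2 and 27 without MB replicate 3.

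At 11 DAP EREB179 (GRMZM2G129674, 1.87 ± 0.24, adjusted p = 0.0014), of the ethylene-responsive element binding family, and the auxin glucosyltransferase iaglu (GRMZM2G024131, 1.88 ± 0.3, adjusted p = 0.005) were higher, calls that were lost in 1 fit over all libraries. The replication helicase gene MCM6 (GRMZM2G021069) stood at 120 ± 6.66 CPM in MB and 259 ± 26.5 CPM in BM (SD, n = 3; -1.06 ± 0.11, adjusted p = 0.00024). In all, 3052 of 21363 genes differed (1467 higher, 1585 lower), 435 of them by at least 1, and 471 in 1 fit over all libraries. Without BM replicate 1 or 2 the count was 2009 or 1432, and without MB replicate 2 or 3 it was 856 or 1570.

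At 13 DAP the benzoxazinoid synthesis genes CYP71C1 and cyp71c2 were higher in MB and transfer-layer genes lower. CYP71C1 (GRMZM2G172491) stood at 50.6 ± 10.8 CPM in MB and 9.62 ± 1.81 CPM in BM (SD, n = 3; 2.46 ± 0.2, adjusted p = 9.8e-05), and cyp71c2 (GRMZM2G167549, 2.79 ± 0.34, adjusted p = 0.0023; lost in 1 fit over all libraries) and ZCN9 (2.98 ± 0.39, adjusted p = 0.0062) were also higher. Lower were betl10 (GRMZM2G091445, -6.17 ± 0.48, adjusted p = 0.00035), betl2 (-5.42 ± 0.67, adjusted p = 0.0072) and esr2 (-5.19 ± 0.45, adjusted p = 0.0022), and betl3 was 173 times lower (95% counting interval 47.8 to 1420). Transfer-layer genes summed to 10.9 ± 8.77 CPM in MB and 418 ± 130 CPM in BM. In all, 5430 of 20461 genes differed (3120 higher, 2310 lower), against 231 and 558 in 1 fit over all libraries. Of the 1166 that differed by at least 1, 404 were higher and 762 lower, and the count was 3184 without BM replicate 2.

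In endosperm at 5 DAP transfer-layer genes were lower in MB as well. Both tcrr-1 (-4.62 ± 0.56, adjusted p = 0.0065) and the aquaporin gene TIP3-1 (GRMZM2G305446, -4.51 ± 0.26, adjusted p = 1.1e-05) were lower, and mn1 stood at 14 ± 13.6 CPM in MB and 310.5 ± 96.6 CPM in BM (SD, n = 3; -4.51 ± 0.81, adjusted p = 0.028). The call of mn1 was lost without any 1 of the BM replicates and without MB replicate 1 or 3. The malic enzyme gene me (GRMZM2G118770) was higher (1.33 ± 0.25, adjusted p = 0.0085), as was prp2 (GRMZM2G102356, 1.96 ± 0.11, adjusted p = 8.7e-06). Transfer-layer genes summed to 408 ± 299 CPM in MB and 3136 ± 525 CPM in BM. In all, 4200 of 19724 genes differed (1786 higher, 2414 lower), 1420 of them by at least 1, against 237 and 585 in 1 fit over all libraries. Without BM replicate 1, 2 or 3 the count was 2682, 2436 or 2609.

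**Figure D4:**
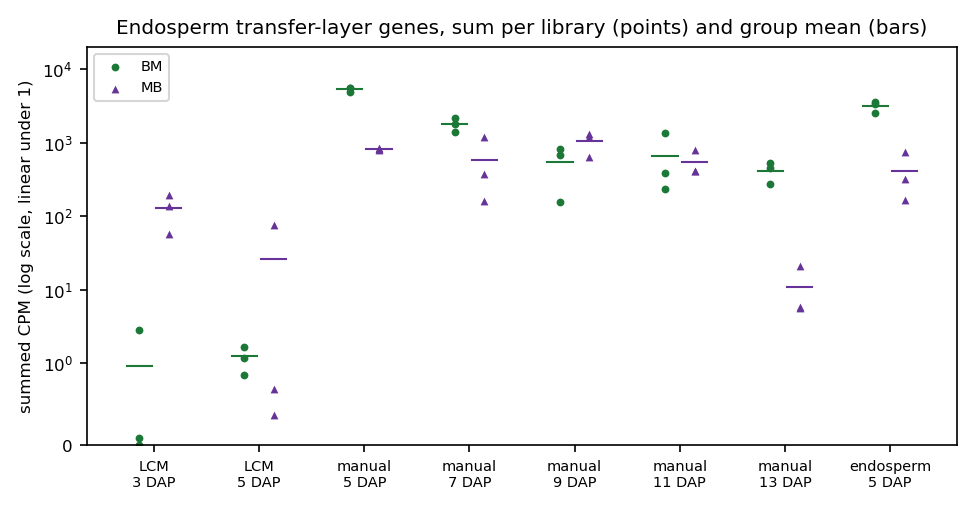
Summed CPM of 14 transfer-layer genes in each library (circles BM, triangles MB; log axis above 1 CPM) with a bar for each group mean, by sample kind. BM manual embryos at 5 DAP reach 5376 CPM on average, MB 816 CPM, and LCM embryos at 5 DAP lie at 1.68 CPM or below apart from MB replicate 3, at 77 CPM.

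Whether the reciprocal difference itself varied was tested with interaction terms. Between endosperm and manual embryo at 5 DAP it differed for 4575 of 23153 genes (2617 positive, 1958 negative, against 1543 and 3073 on FPKM and 202 and 270 in 1 fit over all libraries). The dose of each line's genome differs between the crosses in endosperm, and this term cannot separate that from other causes. Between manual embryos at 13 and 5 DAP the reciprocal difference varied for 5558 of 23141 genes (2772 positive, 2786 negative, against 1717 and 3911 on FPKM and 291 and 466 in 1 fit over all libraries). Between LCM and manual embryos at 5 DAP the reciprocal difference varied for 1310 of 22660 genes (789 positive, 521 negative), and DESeq2 gave 2631. That last count was 540, 640 or 593 without BM manual replicate 1, 2 or 3 and 472, 585 or 446 without MB manual replicate 1, 2 or 3.

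A few genes differed between the crosses in the same direction in at least 5 of the 8 sample kinds. They were 7 genes higher and 12 genes lower in MB, where 0.135 and 0.208 would be met by independent draws over 24830 genes. Those draws give every gene the same chance of a call within a kind. Real genes differ in abundance and spread, and sample kinds may share differences. More genes than drawn were therefore likely, and the excess is not a test. GRMZM2G004932, which has no name and was singled out after its values were seen, was higher in 6 kinds (median 0.45 over all 8). ra3 (GRMZM2G014729), a trehalose phosphate phosphatase gene, was lower in 5 kinds, by -5.52 ± 0.58 in LCM embryos at 5 DAP, -3.26 ± 0.38 in manual embryos at 5 DAP and -2.98 ± 0.35 in endosperm. Sod4A was lower in 5 kinds and mips2 higher in 5, and GRMZM2G175818, an acyl carrier protein gene, was higher in 5 by 0.28 to 0.93. aba1 (GRMZM2G136910) was lower in 4 embryo kinds (-7.98 ± 1.46 in LCM embryos at 5 DAP) and higher in endosperm (1.8 ± 0.32). Its call in LCM embryos was lost without a filter, on FPKM and without BM replicate 1 or 2 or any 1 MB replicate, and its call in endosperm in 1 fit over all libraries and without BM replicate 2. Other settings gave 29 higher and 25 lower (DESeq2), 16 and 20 (no filter), 1 and 7 (1 fit over all libraries) and 8 and 5 (limma on FPKM).

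**Figure D5:**
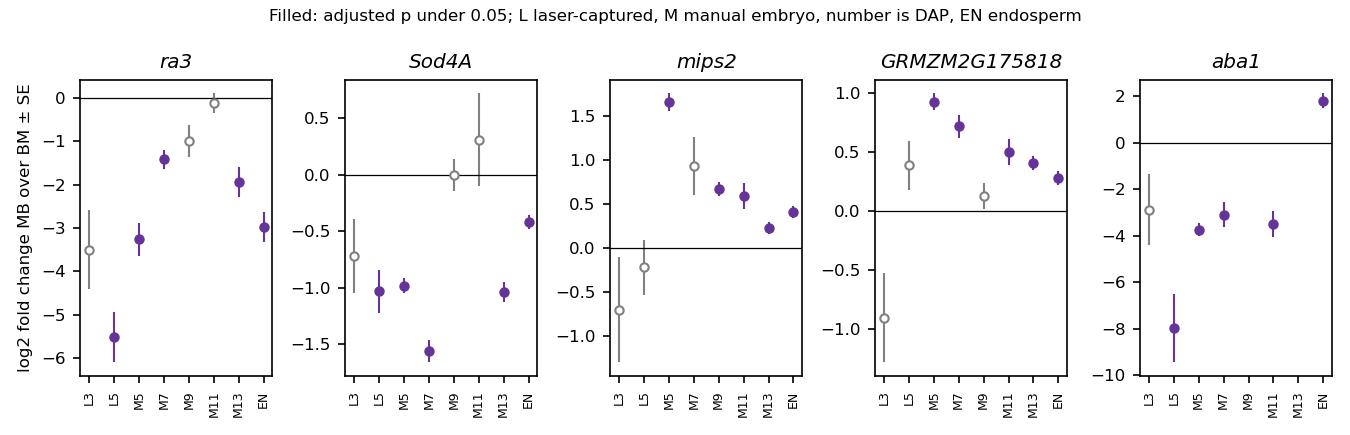
log2 fold change MB over BM ± SE of the 5 genes with a name that were called the same way in most sample kinds, by sample kind on the horizontal axis, filled where the edgeR adjusted p is under 0.05. ra3, Sod4A, mips2 and GRMZM2G175818 keep 1 direction in 5 kinds each, and aba1 lies at -3.73 in manual embryos at 5 DAP.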

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

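The tests in this part were chosen before the data were examined.

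In 3 cases the reciprocal difference, MB over BM, differed between groups by an edgeR interaction test. It differed between endosperm and manual embryo at 5 DAP for 4575 genes, where the highest other split gave 1149. It differed between manual embryos at 13 and 5 DAP for 5558 genes, where the highest other split gave 1468. It differed between LCM and manual embryos at 5 DAP for 1310 genes, where the highest other split gave 677. In each case 1 of 60 splits, the real one, gave as many genes. These splits mix the crosses within each sample kind, so they break the reciprocal difference itself along with the interaction. They cannot tell an interaction from a reciprocal difference that is the same in both groups. The count of 1310 was 540, 640 or 593 without BM manual replicate 1, 2 or 3 and 472, 585 or 446 without MB manual replicate 1, 2 or 3.

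For each of the age, collection and tissue comparisons, 1 of 60 splits, the real one, gave as many genes, a share under 0.05. This speaks against chance for a difference as such, not for the size of each count. For LCM embryos at 5 against 3 DAP the real split gave 1993 and the highest other 1. For manual embryos at 7 against 5 DAP these were 9333 and 0, at 9 against 7 DAP 8722 and 105, at 11 against 9 DAP 5722 and 3192, at 13 against 11 DAP 1394 and 51 and at 13 against 5 DAP 14658 and 1. For LCM against manual embryos they were 17321 and 0, for endosperm against manual embryos 18499 and 3 and for endosperm against LCM embryos 17356 and 0.

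For the reciprocal comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real split and the highest other gave 3 and 0 genes for LCM embryos at 3 DAP and 1289 and 0 at 5 DAP. For manual embryos they gave 6005 and 0 at 5 DAP, 1794 and 0 at 7 DAP, 3052 and 2 at 11 DAP and 5430 and 34 at 13 DAP, and for endosperm 4200 and 0. At 9 DAP the real split gave 6 and another gave 1766, which points to a structure of the samples, and 2 of the 10 splits gave as many as the real one.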

How the results depend on the processing

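The alternatives were chosen before the data were examined, apart from the fit without both LCM libraries at 3 DAP that stood apart. Of 632 results for named genes under the alternatives, 11 values reversed, all on FPKM, and of 187 list medians 1 did. Few reversals were likely, since many named genes were picked for large called changes and a reversal needed a call. The share of called genes that were higher was less steady. For LCM at 5 against 3 DAP it was 28.8% in the main fit, 29.4% with RLE size factors and 61.1% on FPKM. For 13 against 11 DAP it was 56.1%, 58.5% with RLE size factors and 18.4% in 1 fit over all libraries. On FPKM dek1 was at -0.06 for 9 against 7 DAP and 0.10 for 11 against 9 DAP. For LCM against manual embryos cr4 was at -0.66, sal1 at -0.62, dmt105 at -0.69, met2 at -0.48, mop1 at -0.16, see1 at -0.48 and the ribosomal protein median at -0.12. For endosperm cr4 was at -0.26 against manual and 0.40 against LCM embryos, and mez1 at -0.58 against LCM embryos. Leaving out 1 library kept 6967 of 7296 named-gene values on their side of the threshold, with 252 no longer called and 77 newly called.

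Counts moved more. In 1 fit over all libraries they were 10114 for LCM at 5 against 3 DAP, 5240, 4731 and 2359 for manual embryos at 7 against 5, 9 against 7 and 11 against 9 DAP, 7583 and 3630 for MB over BM in LCM at 3 and 5 DAP, 1546, 241, 471 and 789 in manual embryos at 5, 7, 11 and 13 DAP and 822 in endosperm. That fit gave 472 and 757 for the interactions with tissue and age, and 1 gene higher and 7 lower in MB in at least 5 kinds; it shares 1 spread over all libraries, which differ in spread. DESeq2 gave 3613 for LCM at 5 against 3 DAP, 3422 for 13 against 11 DAP, 292, 2250 and 127 for MB over BM in LCM at 3 and 5 DAP and at 9 DAP, 2631 for the interaction with collection, and 29 higher and 25 lower. A log2 fold change of at least 1, stricter by construction, left 2833, 2522, 965, 199 and 6654 for 7 against 5, 9 against 7, 11 against 9, 13 against 11 and 13 against 5 DAP, 11222 for endosperm against manual embryos, 1955, 475, 3, 435 and 1166 for MB over BM at 5, 7, 9, 11 and 13 DAP, 1420 in endosperm and 1839 and 2252 for the interactions with tissue and age. limma on FPKM gave 23, 1070 and 1 for MB over BM in LCM at 3 DAP and at 7 and 9 DAP, and 5 genes lower in at least 5 kinds. No filter on low counts gave 31 and 50 for MB over BM in LCM at 3 DAP and at 9 DAP, and 16 higher and 20 lower. Without both LCM libraries at 3 DAP that stood apart, LCM at 5 against 3 DAP gave 3024 and MB over BM at 3 DAP 1. Where 4 of 6 libraries sufficed, 1222 genes were newly detected in LCM at 5 DAP. With an estimated correlation camera called the lists of meristem, starch, endosperm storage regulators and basal transfer in 0 comparisons each (smallest adjusted p = 0.346). Except where the construction shows it, the cause was not tested.

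With the replicate number as a block 13 against 11 DAP gave 210, MB over BM at 9 DAP 98 and 22 genes were higher in at least 5 kinds. The numbers were not shown to pair the libraries: in 0 of 24 sets of groups did all same-number pairs correlate above 0.1. The cause was not tested.

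Leaving out 1 library gave 1109 to 2297 for LCM at 5 against 3 DAP, 8178 to 9618 for 7 against 5, 7719 to 9395 for 9 against 7, 3958 to 6160 for 11 against 9, 106 to 3066 for 13 against 11 and 14210 to 15148 for 13 against 5 DAP. It gave 17086 to 17725 for LCM against manual, 18394 to 19020 for endosperm against manual and 17256 to 17755 for endosperm against LCM embryos. For MB over BM it gave 0 to 2 and 239 to 1820 in LCM at 3 and 5 DAP, 4118 to 6958, 419 to 3492, 0 to 27, 856 to 3871 and 3184 to 5232 in manual embryos at 5, 7, 9, 11 and 13 DAP and 2436 to 4750 in endosperm. For the interactions it gave 3555 to 4667 (tissue), 4482 to 5649 (age) and 446 to 1933 (collection). For detection, 1 replicate number was left out of every group at a time, and all libraries that remained had to pass. Counts of detected genes could therefore not fall below the main ones. They ran from 13410 to 14833 and 15857 to 16221 in LCM at 3 and 5 DAP, 18808 to 19510, 18772 to 18912, 18320 to 18361, 18784 to 19018 and 18104 to 18281 in manual embryos by age and 17834 to 18030 in endosperm. Newly detected genes ran from 1853 to 3356 in LCM at 5 DAP and 576 to 1045, 380 to 428, 338 to 464 and 78 to 111 at 7, 9, 11 and 13 DAP. Libraries at 7130090 to 21698127 counts and the wide spread of LCM replicates limit what can be called. The median of all genes on FPKM was 0.21 for LCM at 5 against 3 DAP, 0.14, 0.19 and 0.12 for MB over BM in LCM at 3 and 5 DAP and manual embryos at 5 DAP and -0.18 and -0.11 for the interactions with age and tissue. In the main fits these medians were -0.02, 0.02, 0.02, 0.01, -0.07 and 0.03.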

Other observations

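All tests of explanations in this part were chosen only after the results were seen.

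Several gene groups moved in ways not described with the comparisons. Cyclin genes fell in 8 of 10 cases and rose in 1 between 5 and 13 DAP, and cell wall genes rose in 9 of 19 cases and fell in 8. Heat shock genes rose in 7 of 25 cases and fell in 7 over the same time. In the small photosynthesis family list rbcS fell by 3.08 on the log2 scale between 5 and 13 DAP and Cab-m7 was 89.4 times lower at 13 DAP (95% counting interval 16 to 3530), while the ferredoxin gene FDX6 rose by 1.04 ± 0.26. Among cytokinin genes 10 of 18 were lower in endosperm than in manual embryos, with RR9 at -5.65 ± 0.25 and RR7 at -5.47 ± 0.48, and CKX12 was higher at 2.3 ± 0.5. Cell wall genes were lower in LCM than in manual embryos in 12 of 19 cases.

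Transfer-layer genes in manual embryos at 5 DAP stood at 126 to 260% of their endosperm level (median 167% over 14 genes), and 11 of the 14 were under 1 CPM in LCM embryos. Carry-over of endosperm in the proportions of the endosperm libraries is argued against: 29 other abundant endosperm genes that LCM embryos lack stood at a median of 32.5%, a lower quartile of 4.72% and an upper quartile of 79.1%, and gz27 at 0.212%. Carry-over of basal endosperm cells alone may be the source, since the 14 genes moved together within groups (median pairwise r = 0.93 over 30 manual libraries). Expression in the embryo or suspensor under a common regulator would give the same value and stays open, as does the difference between the parents. The r pools all manual ages and may rest mostly on later ages than 5 DAP. The summed level at 5 DAP was 5376 ± 363 CPM in BM and 816 ± 25.4 CPM in MB, against 575 ± 541 CPM in MB at 7 DAP. Related members such as bap-3a and bap-3b may also share reads, which would raise r.

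Whether a later stage of MB embryos accounts for part of the reciprocal differences at 5 and 13 DAP stays open. Across genes, which are not independent replicates, MB over BM went with the change between neighbouring ages at rho = 0.46 at 5 DAP (highest other split 0.37; slope 0.57 against 0.176) and 0.56 at 13 DAP (0.52; 1.238 against 0.529), although both share libraries with the age comparison. The other splits mix the crosses and still hold part of the reciprocal difference. Their lower slopes were therefore likely for any cause of that difference and do not speak for a later stage. For 7, 9 and 11 DAP the change was taken across the age: 9 against 5, 11 against 7 and 13 against 9 DAP. At 7 DAP (0.48, highest other 0.51, slope 0.199 against 0.147) and 11 DAP (0.32, highest other 0.26, slope 0.175 against 0.179) the splits leave it open. At 9 DAP rho was -0.05 (highest other 0.1, slope -0.067 against 0.056), which gives no sign of a later stage. Yet the single intervals disagreed there, with rho -0.17 for 9 to 11 DAP and 0.32 for 11 to 13 DAP, so it stays open. Of genes called in both comparisons, 84.2% of 3382 had the same direction at 5 DAP, 90.7% of 1375 at 7 DAP, 92% of 1308 at 11 DAP and 95.4% of 658 at 13 DAP, but 33.3% of 3 at 9 DAP. What these shares would be without a difference in stage was not computed. At 11 DAP the neighbouring intervals disagreed: rho was 0.61 against the change from 9 to 11 DAP (99% of 1956 genes in the same direction) and -0.34 against that from 11 to 13 DAP (14% of 314), both with the 11 DAP libraries in common. A larger share of embryo cells in the MB libraries at 5 DAP stays open. Of 739 genes with at least 16 times more RNA in LCM and in manual embryos than in endosperm, 235 (31.8%) were lower in MB and 164 higher. The set holds 3 embryo-surrounding genes such as esr1, too few to account for the 235. Only listed genes were checked, so the set is not shown to be of the embryo alone. The rule for reading this test was changed after its value was seen. The difference between the parents stays open as well.

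At 9 DAP BM replicate 1 grouped with MB replicates 1 and 2, and MB replicate 3 with BM replicates 2 and 3, although all pairs correlated at r = 0.975 to 0.99. An exchange of the labels of BM replicate 1 and MB replicate 3 is argued against: on 37 genes called 1 way at 5, 7, 11 and 13 DAP (22 higher in MB), BM libraries scored -0.011, -0.07 and -0.024 and MB libraries 0.248, 0.287 and 0.43. Different stages of the 9 DAP libraries stay open. The lowest stage score of the first 3 libraries minus the highest of the others was -0.081 over 3607 genes changed between 7 and 11 DAP and -0.011 over 2833 genes changed between 5 and 7 DAP. Both lay within the range of scores inside such a set of 3 (up to 0.176 and 0.164). The source of this grouping stays open, and no biological explanation other than stage was tested.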
